A study of Mus musculus with 12 samples.

How the data were processed

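RNA of normal intestine and tumors from Min/+ mice was measured on 12 single-colour Affymetrix MG_U74Av2 arrays, per the labels. The deposited values are linear intensities, 1 per probe set, for 12488 probe sets; the software that summarised the probes is not given in the sources used here. The deposited intensity of the 4 diet #1 arrays was not scaled to a common level, and between 5109 and 5739 probe sets per array (40.9% to 46.0%) carried the value 50, with 1 probe set per array below it. The deposited intensity of the 8 other arrays had a mean of 1000 on each array and no such floor. Diet and this difference in format coincide, while tissue and genotype are balanced within each diet.

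The analysis removed 66 control probe sets, applied quantile normalization to the linear intensities of the other 12422, raised values under the 20th percentile of the normalized values (44.8) to it, and took log2. A floor of this kind, and the floor in the files, sets the folds of dim genes; for the genes named in the tissue comparison the arrays at either floor are counted. Probe sets with a mean in the lowest 40% were left out, and the brightest probe set stood for its gene. The platform annotation gave 1 gene symbol for 10833 probe sets, several for 396 and none for 1193. Of these, 10817 were matched by Entrez ID to RefSeq names of assembly GRCm38.p6, which changed 0 symbols. This left 6400 features, 5648 with a gene name. Where a gene among those named by the rule had another probe set past the filter (14 of 84 genes, 15 probe sets), 3 of the 15 had the opposite sign, none of them past the threshold. Coordinates were not used here.

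Tissue was tested with limma 3.58.1 in R 4.3.3 with tissue, diet and genotype as terms. Genotype, diet and the interactions were tested with the sample code as a random block (duplicateCorrelation), with a correlation within codes of -0.16 for genotype and diet; a negative value makes differences between codes easier to call. Diet was tested with an F test and then by pairs. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The 32 gene lists (934 entries) were fixed before the data were examined, as were the tests, the alternatives and the rule for genes named. Of these lists, 29 had at least 5 measured members and were tested with camera at a preset correlation of 0.01. For genotype the blocked statistics were used (cameraPR). The lists were tested again with an estimated correlation, for genotype with camera and without the block. Lists covered regeneration, Wnt targets, cell cycle, nucleolus, heat shock, epithelial lineages, metabolism, gut segments, stroma, immune cells, imprinted and folate genes, pancreas, and blood.

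The rule for named genes took, for tissue, the 10 largest increases and 10 largest decreases among named genes past the threshold with the same direction in all 6 code pairs, and of each list the 3 members past the threshold with the largest difference. For genotype and each pair of diets it took the 5 largest changes each way among those past the threshold, or, where fewer than 5 features passed, the 5 named genes of smallest p; for interactions, the 5 of smallest p. Dnmt1 and Apc were added. Genotype calls of probe sets that match several genes fall outside the rule and were named after their values were seen. Other genes printed as list examples (Clu, Ccnd1, Tff3, Car1) were chosen after their values were seen.

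The sample codes, taken from the titles, pair the arrays by label. Deviations from the tissue means correlated at 0.46 to 0.68 within every code. After diet and genotype were removed, the correlation was -0.57 to -0.38, where independent arrays give -0.43. The shared diet, with its file format, and genotype therefore carried the correlation, and the values show no pairing by code beyond them. No arrays were near-duplicates: the highest correlation between arrays of a tissue was 0.982.

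Alternatives were median scaling, no normalization, floors at the 5th and 40th percentiles, no filter, removal of the lowest 60%, every probe set, trended robust variances, other blocks and thresholds, and each array left out in turn. Alternatives without diet #1, without diet #2, within each diet and without pancreas genes in other lists were added after the data were seen. On data simulated from the real means and spreads with 200 of 6400 features changed, the tissue fit recovered 49.3% of 1.5-fold, 82.1% of 2-fold and 97.0% of 4-fold changes, with 8.43% of its calls false. The genotype fit recovered 62.7%, 83.6% and 92.4%, with 10.7% of calls false, and the diet fit 40.3%, 77.6% and 97.0%, with 11.2% false. The tissue by diet fit recovered 22.7% of 4-fold changes and 0 of the smaller ones. Both changed lists and 0 of 8 unchanged lists were called for tissue and for genotype. The simulated features varied independently, so these lists could not show false calls that come from correlation between genes. The simulated arrays were independent too, with no effect shared within a code. The genotype and diet recovery therefore does not cover spread between codes. The false share exceeded the nominal threshold in the tissue, genotype and diet fits. Figures were drawn with matplotlib.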

Results

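The series profiled RNA from intestine and intestinal tumors of male Min/+ mice, 91 days old, which carry a mutant Apc allele and develop intestinal adenomas. Each RNA sample was hybridised to 1 Affymetrix MG_U74Av2 oligonucleotide array, giving 12 arrays with 12488 probe sets each. There were 6 normal intestine arrays and 6 tumor arrays. Each tissue was represented by 3 numbered diets and, within each diet, by a heterozygous (Dnmt+/-) and a wild type (Dnmt+/+) genotype of a DNA methyltransferase gene, with 1 array per combination. A sample code was shared by the normal and the tumor array of each diet and genotype, which made 6 code pairs. The labels do not say that a code stands for a single animal or that arrays came from separate animals, so p-values measure the spread between these samples, part of which may be technical. The number of arrays limits the precision of every value below. Mean deposited intensity lay between 306 and 403 on the 4 arrays of diet #1 and was 1000 on the arrays of diets #2 and #3.

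The first principal component of the 6400 features tested carried 46.5% of the variance and set the arrays of diet #1 apart from those of diets #2 and #3. Normal and tumor arrays separated along the second component, which carried 23.6%.

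**Figure D1:**
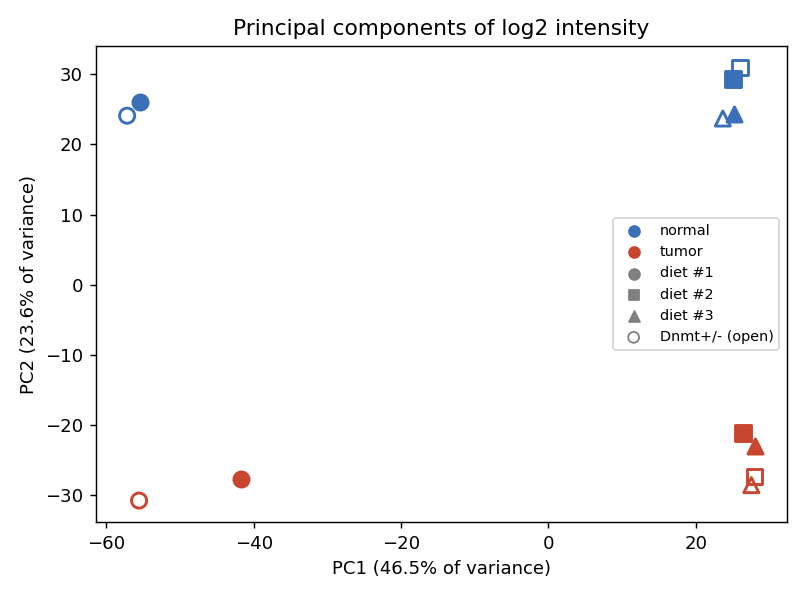
Principal components of log2 intensity over the features tested, with PC1 on the horizontal and PC2 on the vertical axis and each point an array. Diet #1 arrays lie left on PC1 (46.5% of variance), and normal arrays lie above tumor arrays on PC2 (23.6%).

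The central comparison asked which transcripts changed between normal intestine and tumor. Tumors carried far more transcript of the mast cell proteases Mcpt1 and Mcpt2 and of Fabp6, and less of Fbp1 and Slc2a5. Mcpt2 and Mcpt1, proteases of mucosal mast cells, were 103-fold and 61.1-fold higher in tumor (log2 difference 6.68 ± 0.34 and 5.93 ± 0.34, SE, n = 6 arrays per tissue; limma adjusted p = 2.81e-06 and 5.62e-06). Fabp6, which binds bile acids in ileal enterocytes, was 90.0-fold higher (6.49 ± 0.22, limma adjusted p = 2.71e-07). Fbp1, an enzyme of gluconeogenesis, and Slc2a5, the fructose transporter, were 7.65-fold and 7.58-fold lower (-2.93 ± 0.26 and -2.92 ± 0.26, limma adjusted p = 5.78e-05 and 6.27e-05). All these differences had the same direction in all 6 code pairs.

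Of the 6400 features, 2251 differed between tissues by limma at an adjusted p under 0.05, 1167 higher and 1084 lower in tumor. Among them, 521 changed at least 2-fold, 299 upward and 222 downward. The direction was the same in all 6 code pairs for 1926 of the 2251, which were called on these same pairs; in 1912 of them no pair had both arrays at a floor. The balance of directions depended on the scaling: 847 rose and 1551 fell with median scaling, where the median feature shifted by -0.099, and 1358 rose and 729 fell on the values as deposited, where it shifted by 0.13. Within single diets, fitted alone on 4 arrays, 42 features were called in diet #1, 1235 in diet #2 and 593 in diet #3.

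The other large increases included secreted and epithelial proteins, and like the decreases after them had the same direction in all 6 code pairs, except that both arrays of a diet #1 pair were at the file's floor for Ephx1, so that 5 pairs show its direction. Wfdc18 was 35.6-fold, complement factor I (Cfi) 30.9-fold and the laminin chain gene Lamb3 19.1-fold higher in tumor. Retnlb, a goblet cell product, was at the measurement floor in all 6 normal arrays and 26.2-fold higher in tumor (log2 difference 4.71, limma adjusted p = 0.000112), a value set by that floor and by the scaling: the difference was 3.87 with median scaling and 3.56 with the higher floor. Pla2g2a, a secretory phospholipase of Paneth cells, was 18.3-fold higher, Anxa1 17.7-fold and the keratin gene Krt7 16.9-fold. Some normal arrays were at the floor for these genes, 1 of 6 for Mcpt1 and Anxa1, 2 of 6 for Mcpt2, Fabp6, Wfdc18 and Lamb3 and 3 of 6 for Cfi, so that those folds depend on the floor and the scaling. Second probe sets differed by 2.32 for Lamb3 and by 2.66 and 4.31 for Anxa1 (log2), all past the threshold. The other large decreases were in Cyp3a11 (6.42-fold), the lipoprotein receptor gene Scarb1 (6.17-fold), the D-amino acid oxidase gene Dao (6.15-fold), Prxl2a (6.06-fold), the glutathione transferase genes Gsta4 (6.06-fold) and Gstm6 (5.53-fold; -1.80 by a second probe set, log2), the epoxide hydrolase gene Ephx1 (5.63-fold, with 1 normal and 2 tumor arrays at the floor) and the glucose-6-phosphatase gene G6pc (5.40-fold). A second probe set of Prxl2a differed by -0.23 and did not pass (limma adjusted p = 0.48).

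**Figure D2:**
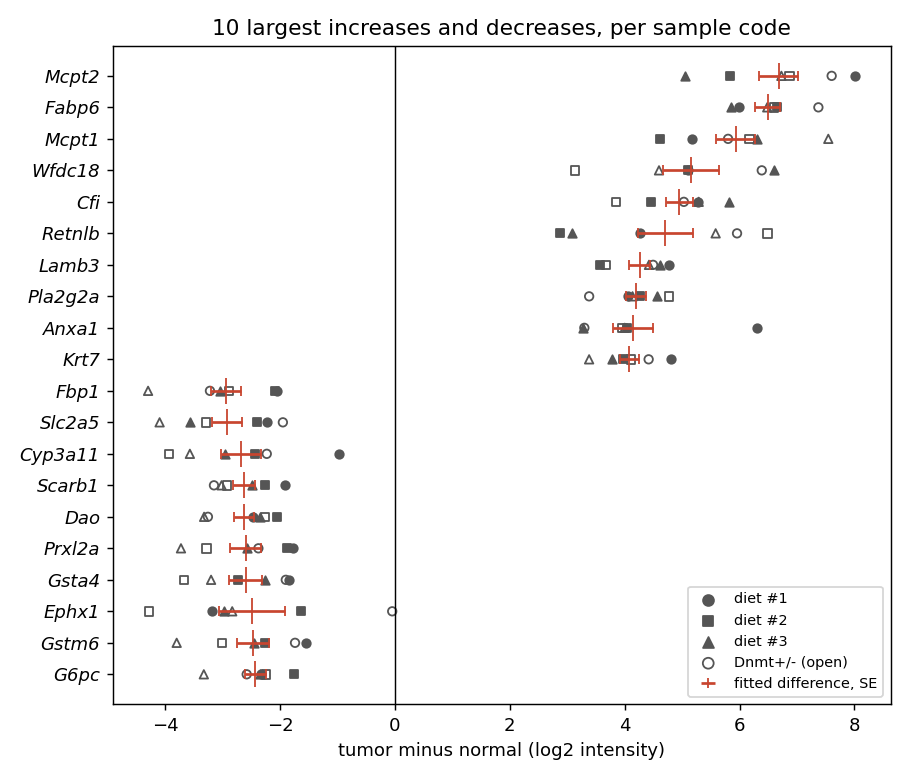
Tumor minus normal log2 intensity (horizontal axis) for the 10 largest increases and 10 largest decreases, 1 row per gene. Symbols are the 6 code pairs by diet and genotype and red bars the fitted difference with its SE, from 6.68 for Mcpt2 to -2.93 for Fbp1.

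All 18 measured members of the regenerative and fetal epithelium list rose, both over all features and adjusted over the list alone (median 2.01, camera adjusted p = 2.33e-13). They included the calcium-binding protein gene S100a6, 13.4-fold higher, and Clu, 9.42-fold higher. Of 18 Wnt target genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone), among them Gpx2 (5.74-fold), the matrix protease gene Mmp7 (4.72-fold), Plaur (2.20 ± 0.24, log2) and the cyclin gene Ccnd1 (2.51-fold). The Wnt list passed camera (adjusted p = 0.000509) and did not with an estimated correlation (adjusted p = 0.053). Of 55 cell cycle genes, 36 rose and 1 fell (38 and 1 adjusted over the list alone), with Rrm1 3.37-fold, Kif20a 3.02-fold and Cks1b 2.63-fold higher (camera adjusted p = 2.43e-10, and adjusted p = 0.053 with an estimated correlation). Rrm1 did not pass in 8 of 12 fits with an array left out (1.33 to 2.24, log2). Of 26 genes of nucleolar and ribosome assembly, 21 rose, including Gnl3 (2.57-fold), Nhp2 (2.54-fold) and Gar1 (2.52-fold), and camera called the list (adjusted p = 4.91e-09). Of 28 members of the heat shock and unfolded protein list, 16 rose and 2 fell (18 and 3 adjusted over the list alone). The list passed camera (adjusted p = 0.000462) and did not with an estimated correlation (adjusted p = 0.053). Hspa1b was 2.87-fold higher. Ier3 (2.32-fold) and Egr1 (2.26-fold), which are on the list but are not heat shock genes, were higher too. Egr1 did not pass in 8 of 12 fits with an array left out (0.79 to 1.49, log2).

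Of 9 Paneth cell genes, 5 rose (6 adjusted over the list alone), led by Pla2g2a and the pentraxin gene Mptx1, 6.18-fold higher (camera adjusted p = 0.000105, and adjusted p = 0.053 with an estimated correlation). Of 13 goblet cell genes, 8 rose, including Foxa1 (5.65-fold) and Spink4 (3.39-fold), while Tff3 differed by 0.049 ± 0.079 (list adjusted p = 0.00693, and adjusted p = 0.053 with an estimated correlation). Of 11 enteroendocrine genes, 7 fell, among them the hormone genes Cck (5.29-fold), Sst (3.72-fold) and Gip (3.62-fold) (adjusted p = 0.000462, and adjusted p = 0.053 with an estimated correlation).

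Of 43 genes of xenobiotic and retinoid metabolism, 29 fell and 2 rose (30 and 2 adjusted over the list alone; camera adjusted p = 1.08e-09), and Akr1b8 went the other way, 7.33-fold higher. Of 44 oxidative phosphorylation genes, 34 fell and none rose (35 fell adjusted over the list alone), with Cox7a1 2.93-fold, Sdha 2.00-fold and Ndufa5 1.91-fold lower (adjusted p = 3.80e-11, and adjusted p = 0.086 with an estimated correlation). Of 24 fatty acid oxidation genes and PPAR targets, 18 fell and 2 rose, with Ehhadh 4.15-fold, Pdk4 2.94-fold and Crat 2.43-fold lower (camera adjusted p = 1.25e-05, and adjusted p = 0.088 with an estimated correlation). Of 20 lipid absorption genes, 12 fell and 1, Fabp6, rose; Slc27a2 was 4.52-fold lower (adjusted p = 0.000488, and adjusted p = 0.28 with an estimated correlation). Of 23 brush border genes, 8 fell and 3 rose, the risers including the phosphate transporter gene Slc34a2, 6.61-fold higher (list adjusted p = 0.039, 0.52 with an estimated correlation, 0.061 with the codes as a block and 0.17 without the diet #1 arrays). The Slc34a2 difference of 2.73 (log2) became 3.53 without the heterozygous normal array of diet #1 and 2.09 without that of diet #2, and did not pass in 8 of 12 fits with an array left out (adjusted p up to 0.096). Of 5 proximal intestine markers, Gip and the lactase gene Lct (1.91-fold) fell (adjusted p = 0.047, adjusted p = 0.12 with an estimated correlation, 0.0505 with the codes as a block, 0.064 with median scaling, 0.0515 with the lower floor and 0.053 without the diet #1 arrays). The mean of these 5 genes was 12.1 and 12.2 on the normal arrays of diet #2, which carried pancreas genes, against 9.56 to 10.5 on the other normal arrays, and without the diet #2 arrays the list median was -0.48 (adjusted p = 0.49).

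Stromal and immune lists moved in both directions. All 6 measured mast cell genes rose, with the carboxypeptidase gene Cpa3 7.91-fold higher (1.79 by a second probe set, log2) and 5 of 6 normal arrays at the floor (camera adjusted p = 3.50e-05, and adjusted p = 0.062 with an estimated correlation). Of 38 fibroblast and extracellular matrix genes, 20 rose and 2 fell (22 and 2 adjusted over the list alone), including Plat (7.09-fold), Col1a1 (3.11-fold; a second probe set differed by 0.89, log2, and passed) and Mmp13 (3.07-fold); camera called the list (adjusted p = 1.90e-06). Of 27 interferon response genes, 17 fell and 1 rose (20 and 1 adjusted over the list alone), with the immunoproteasome gene Psmb9 2.98-fold and Ifi35 2.80-fold lower and Ifitm3 3.04-fold higher (adjusted p = 5.72e-07, and adjusted p = 0.11 with an estimated correlation). Of 11 T and NK cell genes, 4 fell, among them Ccl5 (2.79-fold), Trgv4 (2.25-fold) and Cd4 (2.20-fold; -0.49 as deposited, log2, which did not pass) (adjusted p = 0.026, and adjusted p = 0.27 with an estimated correlation). That call was also lost with median scaling (adjusted p = 0.24), as deposited (0.067), with the higher floor (0.11), without the diet #1 arrays (0.085) and without the diet #2 arrays (0.10). Of 8 adipose genes, 6 fell, with Car3 3.87-fold, Adipoq 2.97-fold and Cidec 2.84-fold lower (adjusted p = 0.00621, and adjusted p = 0.20 with an estimated correlation).

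The lists that camera did not call still held single genes that passed. Saa3 was 10.5-fold, Cxcl5 4.02-fold and Mmp12 3.25-fold higher within the myeloid and inflammatory list, where 8 of 21 genes rose and 4 fell (8 and 5 adjusted over the list alone; list adjusted p = 0.20). In the folate, one-carbon and DNA methylation list, 5 of 17 rose and 2 fell (8 and 3 adjusted over the list alone, list adjusted p = 0.13). The folate transporter gene Slc46a1 was 5.18-fold lower and Uhrf1 1.88-fold higher. Ggh was 2.64-fold higher but did not pass in 7 of 12 fits with an array left out. Among 13 imprinted genes 3 rose, Phlda2 (2.17-fold), Dcn (1.65-fold) and Cdkn1c (1.61-fold) (list adjusted p = 0.42). Among 10 endothelial genes 3 rose and 1 fell (list adjusted p = 0.84), with Cdh5 2.78-fold higher and Emcn 1.63-fold lower. Edn1, also on that list, was 1.69-fold higher but differed by -0.076 with median scaling. Adjusted p was 0.65 for the colon marker list (Ces1d 4.55-fold lower, Car4 2.32-fold higher), 0.82 for smooth muscle (Csrp1 1.43-fold higher, Mylk 1.33-fold lower), 0.58 for enteric nerve (Stmn2 1.41-fold lower), 0.41 for B and plasma cells (Jchain 1.27-fold lower) and 0.062 for MHC class II (H2-Ab1 1.62-fold lower). Stmn2, Jchain and H2-Ab1 did not pass when adjusted over the list alone, and second probe sets of Car4 and Stmn2 differed by -0.51 and 0.090. The exocrine pancreas list had a median of -2.004 with 0 of 13 members passing in limma (adjusted p = 0.062), and its members were high on both normal arrays of diet #2. Too few members were measured to test the Reg family, in which Reg3g (6.50-fold) and Reg3b (2.74-fold; 2.43 by a second probe set, log2) were higher and Reg1 lower (-2.20 ± 0.62, log2; a second probe set differed by -0.62 and did not pass, limma adjusted p = 0.18), the ileal list, in which Fabp6 was the member that passed, and the erythroid list, in which 0 of 2 passed. Among the genes named for lists, 5 of 6 code pairs showed the direction for Slc34a2, Rrm1, Egr1, Csrp1, Adipoq, Reg1, Ces1d and Trgv4 and 4 of 6 for Ggh; for the others all 6 did. In Rrm1, Egr1, Ces1d and Trgv4 the remaining pair had both arrays at a floor. The arrays at a floor on the lower side were 4 of 6 for Saa3 and Ces1d, 3 for Plaur and Car3, and 2 for Akr1b8, Cxcl5, Mmp12, Gnl3, Kif20a, Egr1, Trgv4 and Cd4. They were 1 for Hspa1b, Foxa1, Cdh5, Phlda2, Edn1, Rrm1, Ggh, Slc34a2, Adipoq and Cidec.

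**Figure D3:**
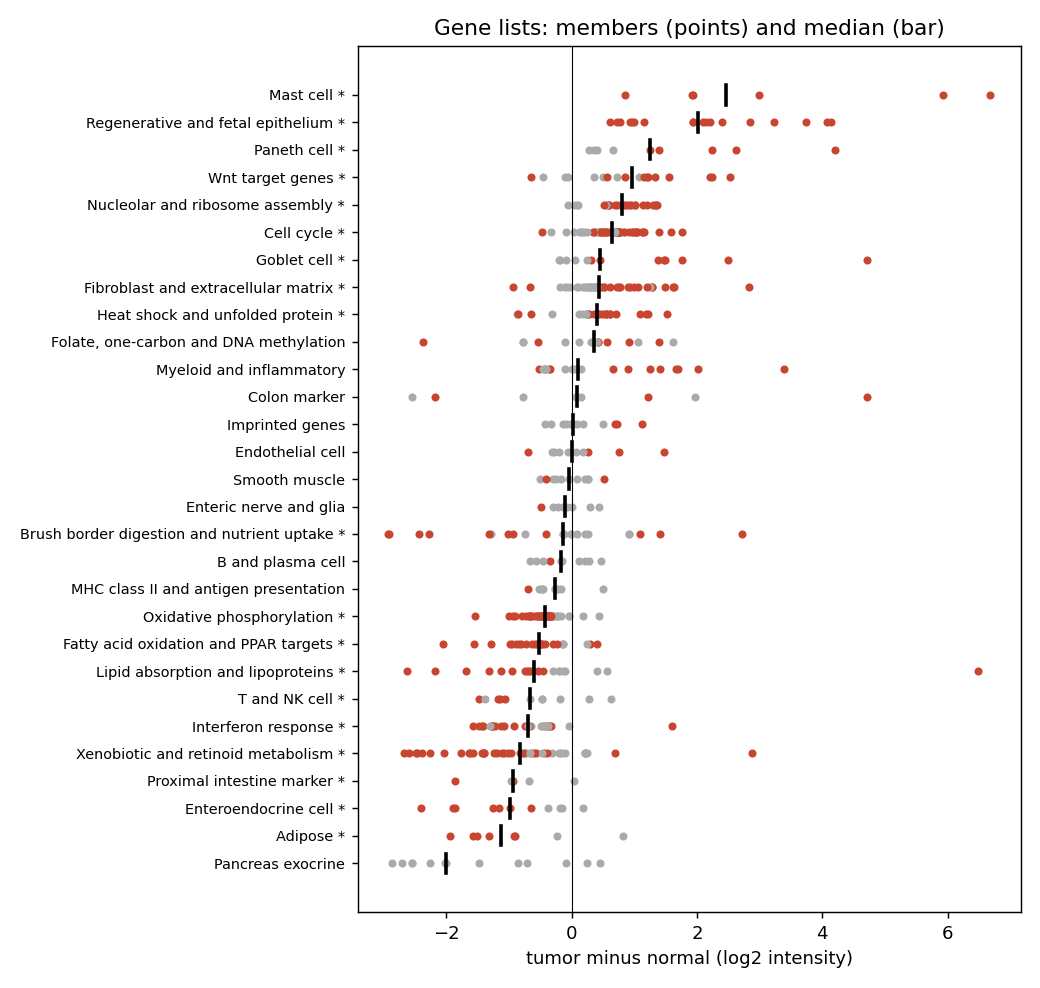
Tumor minus normal log2 intensity (horizontal axis) of each measured list member (points, red where adjusted p was under 0.05) with the list median (black bar); an asterisk marks lists called by camera. Medians run from 2.46 for mast cell genes to -2.004 for exocrine pancreas genes.

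Camera called 19 of 29 lists, 9 up and 10 down, with its preset correlation of 0.01. With a correlation estimated from the data, 4 remained past the threshold: regenerative and fetal epithelium (adjusted p = 0.00423), xenobiotic metabolism, nucleolar assembly, and fibroblast and extracellular matrix (adjusted p = 0.041 each). Without the diet #2 arrays, an alternative chosen after the pancreas signal was seen, 1358 features were called.

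The genotype comparison asked how Dnmt heterozygous tissue differed from wild type. By its brighter probe set, the one tested, Dnmt1 was lower in heterozygous arrays wherever both values lay above the file's floor. The labels do not number the Dnmt gene, nor say whether the probes lie in the altered part of a gene. In diet #2 the deposited intensity was 612 against 776 in normal intestine and 1027 against 1483 in tumor, heterozygous against wild type. In diet #3 it was 491 against 688 and 877 against 1566. The 4 ratios ranged from 56.0% to 78.8% of wild type, with a geometric mean of 68.3% (both tissues of a diet share their codes; exact sign permutation test on the 2 diet means, two-sided p = 0.5, the smallest that 2 diets allow). Over all 12 arrays the limma difference was -0.91 ± 0.35 and did not pass (adjusted p = 0.698). A second, dim Dnmt1 probe set, left out by the filter, did not show this in normal intestine, with 76.0 against 71.6 in diet #2 and 107 against 70.3 in diet #3, heterozygous against wild type. In tumor it read 88.4 against 132 in diet #2 and 12.1 against 15.4 in diet #3. In diet #1, 3 of the 4 arrays were at 50, the file's floor, and the wild type tumor read 251.5. Apc read 182.8 to 328.4 in heterozygous and 138.4 to 306.0 in wild type arrays of diets #2 and #3.

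In the fit with the codes as a random block, a beta globin transcript was called lower and an immunoglobulin transcript higher in heterozygous arrays. Hbb-b2, a beta globin gene, was 2.05-fold lower (-1.04 ± 0.12, SE, n = 6 arrays per genotype; limma adjusted p = 0.040) and lower in all 6 matched comparisons of the same tissue and diet. Both tissues of a diet share their codes, so these 6 comparisons, here and for the genes below, rest on 3 pairs of codes, 1 per diet. Hba-a1, an alpha globin gene, was 1.85-fold lower in all 6 but did not pass (limma adjusted p = 0.088). In all, 3 of 6400 features passed, 1 higher and 2 lower, with 451 at an unadjusted p under 0.05. The other called features were probe sets that match several genes, given here after their values were seen. The probe set annotated to Igk, the immunoglobulin kappa locus, and to a kappa variable gene was 5.18-fold higher with 2 of 6 wild type arrays at the floor (limma adjusted p = 0.043), and that of the beta globin genes Hbb-bt, Hbb-bs, Hbb-b2 and Hbb-b1 was 2.40-fold lower (limma adjusted p = 0.015), each in all 6 matched comparisons. Next in rank by p, Pip4k2a was 0.50 ± 0.09 higher, Pgam1 differed by -0.41 ± 0.08 and Slc8a1 by 0.49 ± 0.11, none of which passed. With arrays taken as independent 1 feature passed, a lower one, so the higher immunoglobulin probe set did not pass. With the mean of both tissues per code 0 passed in limma, with 261 at an unadjusted p under 0.05.

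Gene lists moved little with genotype. The colon marker list was higher in heterozygous arrays (median 0.65, camera adjusted p = 0.00409, adjusted p = 0.43 with an estimated correlation), with 0 of 9 members passing. Without Sycn, which is also on the pancreas list, the median was 0.64 (adjusted p = 0.00378). The median with Sycn was 0.10 in diet #1, 0.62 in diet #2 and 0.97 in diet #3. Retnlb differed by 1.34 ± 0.41 and the carbonic anhydrase gene Car1 by 2.40 ± 0.98. The smooth muscle list was higher (median 0.15, 0 of 11 members passing and 1 adjusted over the list alone, adjusted p = 0.00662, adjusted p = 0.43 with an estimated correlation). The xenobiotic (median -0.095, adjusted p = 0.034), interferon (-0.13, adjusted p = 0.047) and nucleolar (-0.095, adjusted p = 0.047) lists were lower, with adjusted p = 0.43, 0.50 and 0.43 given an estimated correlation. The values with an estimated correlation come from a fit without the block on codes. Without the block and at the preset correlation, 4 lists passed. The interferon median was -0.38 in diet #1, 0.020 in diet #2 and 0.0099 in diet #3. No other list passed (of 29 tested, 10 had an unadjusted p under 0.05). Median, mean and test differed in sign for the uncalled regenerative, MHC class II, enteric nerve, fatty acid oxidation and adipose lists. The called lists were not stable: without the heterozygous tumor array of diet #2 0 lists passed, and without the wild type normal array of diet #2 8 passed.

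The diet comparison covered 3 diets whose composition the labels do not give. The file's format differs between diets, since the values of diet #1 are unscaled and 40.9% to 46.0% of them are 50, with 1 value per array below it, so any difference against diet #1 cannot be told apart from that format. Spink1, a trypsin inhibitor gene, was 67.9-fold lower in diet #2 and 56.6-fold lower in diet #3 than in diet #1 (limma adjusted p = 1.37e-06 and 1.57e-06). Rbm22 was 26.3-fold lower in both, with all arrays of diets #2 and #3 at the floor, so that these folds depend on the floor. Ifitm1 (24.5-fold and 20.97-fold) and C1qbp (21.9-fold and 22.3-fold) were lower in diets #2 and #3, Fcgrt 19.2-fold lower in diet #2 and H2-M1 15.6-fold lower in diet #3. Several increases over diet #1 rest on arrays of diet #1 at 50: Sycn (33.2-fold), P4hb (33.1-fold) and Limk1 (25.3-fold) in diet #2 and Krr1 (19.4-fold) and Grk6 (17.8-fold) in diet #3 had 4 of 4 such arrays. Acsf3 (18.4-fold), Rxrb (17.4-fold) and Ptgds (16.9-fold) in diet #3 had 3. Sycn, Cela1 (30.5-fold) and Pla2g1b (24.5-fold), which are pancreatic products, were high on both normal arrays of diet #2. Spink1 was not, at 6.08 and 6.49 (log2) on those arrays.

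Diets #2 and #3, both scaled, differed less. The deposited values of diet #3 carried more decimals than those of diet #2, and each diet had its own sample codes. A difference between these diets therefore cannot be told apart from separate processing of their arrays. Relative to diet #2, diet #3 arrays carried more Prmt1 (3.12-fold), 1110051M20Rik (2.77-fold), Ptpn1 (2.61-fold), Mmp9 (2.60-fold) and H2-Q10 (2.41-fold). They carried less Jkamp (3.36-fold), Pmel (3.24-fold), the hepatocyte nuclear factor gene Hnf4a (3.06-fold), Fkbp11 (3.05-fold) and P4hb (2.73-fold). The F test over the 3 diets called 3961 of 6400 features; 3476 differed between diets #2 and #1, 3575 between #3 and #1 and 594 between #3 and #2. With arrays taken as independent the last count was 274, on the arrays of diets #2 and #3 alone it was 1492, and with the mean of both tissues per code the F test called 2639.

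The tissue difference was then compared between genotypes and between diets. No feature had a tissue difference that depended on genotype at an adjusted p under 0.05 in limma, and 139 did at an unadjusted p under 0.05. The 5 named genes with the smallest p were Retnlb, Celsr2, Serf2, Mx2 and 1810044D09Rik. The tumor increase of Retnlb was 6.01 in heterozygous and 3.41 in wild type code pairs (difference 2.60 ± 0.47, adjusted p = 1.00). That of Celsr2 was 1.89 against -0.89, of Serf2 -0.96 against -0.31, of Mx2 -0.96 against 0.029 and of 1810044D09Rik 0.16 against -0.87. In simulated data this comparison recovered 0% of 1.5-fold, 20.9% of 2-fold and 62.1% of 4-fold changes.

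The tissue difference depended on diet for 95 features, 10 of them among the 13 exocrine pancreas genes. Prss2, a trypsinogen gene, differed by 2.14 in diet #1, -8.95 in diet #2 and 0 in diet #3 (limma adjusted p = 0.000126), but the 0 is a floor against a floor: Prss2 was at a floor on all diet #3 arrays, on the diet #2 tumor arrays and on the diet #1 normal arrays. The chymotrypsinogen gene Ctrb1 (-5.89 in diet #2 against 0.022 and -0.15), the elastase gene Cela1 (-4.58 against 4.13 and 1.82) and the lipase gene Cel (-6.30 against 0.12 and 0.094) followed, each with the diet #1 and diet #3 values in that order. Krtap5-1 instead stood out in diet #1, at 3.78 against -0.12 and 0.15, with both diet #1 normal arrays at a floor, as for Cela1. Of the 95 features, 28 were most extreme in diet #2 and 60 in diet #1, where values are floored. Without the diet #2 arrays 0 features were called, with 448 at an unadjusted p under 0.05, and without the diet #1 arrays 34 were. The count was 206 as deposited, 208 without a filter and 37 with the stricter filter, and 44 to 331 with each array left out, highest without a diet #1 array.

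**Figure D4:**
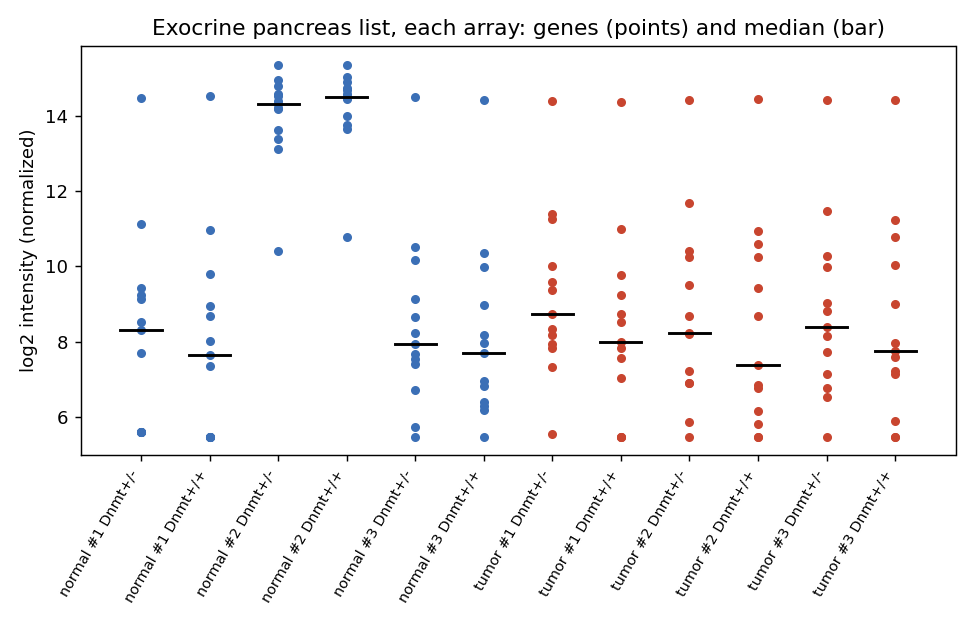
Log2 intensity (vertical axis) of the 13 exocrine pancreas genes on each of the 12 arrays, with points for genes and a bar for the median. For 12 of 13 genes the mean of both diet #2 normal arrays lay over 2 log2 units above that of the other normal arrays.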

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

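Of the tests weighed here, those of separate processing, of an effect of diet #2, and of both explanations for Fabp6 were chosen only after the result was seen.

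The tissue difference varied with diet for 95 features, among them Prss2 (-8.95 in diet #2), Ctrb1 (-5.89), Cela1 (-4.58) and Cel (-6.30), while Krtap5-1 (-0.12 in diet #2) stood out by diet #1. On both normal arrays of diet #2, all 13 exocrine pancreas genes lay above every other normal array, by a median of 6.82 (log2); Prss2 reached 14.4, Ctrb1 15.4 and Cel 15.0. Separate processing shared by all arrays of that diet is argued against by the tumor arrays of diet #2, whose median shift was 1.25% of that in the normal arrays. Handling of the normal samples of diet #2 alone was not tested by this. RNA from pancreas carried along with the tissue may account for it. A further set of 17 pancreas genes was chosen before their values were seen. The 7 measured were higher by a median of 1.80, including Ins2 by 5.26. Of the 7, 1 passed the filter, Ppy, which was 0.54 higher. Ins2, Iapp, Cuzd1 and Gnmt were at a floor on the other normal arrays. These genes could therefore not come out clearly lower, and the sizes of their differences depend on the floor. An effect of diet #2 on normal intestine stays open and cannot be told apart from pancreas RNA, because the same 2 arrays carry both. Zg16, also on the goblet cell list, differed by 0.081. Spink1, a trypsin inhibitor gene on neither set, was not raised with the others. It read 6.08 and 6.49 on the normal arrays of diet #2. On those of diet #3 it read 7.16 and 5.70, and on those of diet #1 13.2 and 12.7. The reason was not tested.

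Fabp6 stood at 11.5 on the wild type tumor array of diet #1 against 12.98 to 13.8 on the other tumor arrays, and was 90.0-fold above normal, while Gip and Lct fell. Its rise was 30.1 times its standard error, which restates the pattern and so decides nothing on fewer mature enterocytes, an explanation that stays open for the lower Lct. Tumors that lay further along the small intestine than the normal tissue could give this pattern; the 3 other ileal markers measured, Cubn, Slc51a and Bcat2, had a median difference of 0.37 with 0 passing, which does not decide it. A further set of 5 distal genes had 0 members on the array. A change of Fabp6 in adenoma itself, the biological alternative, was not tested.

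The colon marker list was higher in heterozygous arrays, by a median of 0.18 in normal and 0.84 in tumor arrays without Sycn, which is also on the pancreas list. The format of diet #1 is argued against, since the median without those arrays was 154% of that with them. Colon tissue in the heterozygous samples may contribute and stays open: 7 further posterior genes, chosen before their values were seen, had a median difference of 0.040, but 0 of 7 lay clearly above the floor, so the bound set in advance was wrong for genes this dim. Car1 read 12.3 and 11.98 on the heterozygous tumor arrays of diets #2 and #3 and 5.57 on that of diet #1. An effect of the Dnmt genotype stays open, as untested.

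Single arrays stood apart in 24 of 244 sets of 6 values (9.84%). The outlier bound used gives about 1 in 20 for independent, normally distributed values. These sets share arrays and some hold floored values, so that rate does not apply to them. Retnlb stood apart with all 6 normal arrays at a floor, and Cpa3 with 5 of 6. On the heterozygous normal array of diet #1, Retnlb, Cdh5, Phlda2 and Trgv4 all read 5.61, the file's floor after normalization, Ier3 10.04, Psmb9 10.3, Saa3 9.01 (others 5.48 to 5.65) and the interferon list 9.53. On the wild type normal array of diet #1, Crat read 9.30 and the B and plasma cell list 10.4. On normal arrays of diet #2, Cdkn1c read 7.53 and the folate list 8.999 (wild type), and Cpa3 5.93 (heterozygous). On the heterozygous tumor array of diet #1, Rrm1, Egr1 and Dnmt1 read 5.57, again the file's floor, Plat 9.77, Foxa1 10.7 and Ndufa5 11.2. On tumor arrays of diet #3, Cfi read 11.6 (wild type), and Ephx1 6.45, Cxcl5 9.93 and Mmp12 10.3 (heterozygous).

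Other splits of the arrays bear on the counts. The real tissue split called 2251 features, and 1 of 100 splits into 6 and 6 (of 462, with the real one) called as many, the highest other 95. Of 32 splits that part all code pairs, 1 did, the highest other 4. Both shares are under the 0.05 set in advance, and the 1 is the real split itself. The other splits leave the tissue difference in their residuals, which can lower their counts. For the gene lists the share was not under 0.05: 6 of 100 splits called at least 19 lists, the highest other 20. The splits of codes are too few for a share under 0.05. For genotype, 3 of 10 splits called at least 3 features, the highest other 408, and 3 of 10 called at least 5 lists, the highest other 6. The split with 408 set diet #2 against diet #3 codes and the diet #1 codes apart by their real genotype. With diet in the fit, its difference is the real genotype difference within diet #1, so the 408 is no measure of chance. Why it exceeded the 3 of the full comparison was not tested. For diet 1 of 15 partitions called 3961, the highest other 2665; for tissue by genotype all 10 splits called at least 0, the highest other 1; for tissue by diet 1 of 15 called 95, the highest other 35.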

How the results depend on the processing

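The alternatives without a diet, within a diet, without a block for the genotype lists, and without pancreas genes in other lists were chosen after the data were seen; the cause of each change was not tested unless stated. The 2251 tissue calls became 1083 without covariates, 521 with a 2-fold minimum, 1343 at the stricter adjusted p, 1358 without the diet #2 arrays (fewer samples), and 42, 1235 and 593 within diets #1, #2 and #3 (fewer samples); leaving out each array gave 1889 to 2180. With the codes as a replicate block, to use the pairing, 2105 features and 18 lists passed; the block ended the calls of the brush border (adjusted p = 0.061) and proximal (0.0505) lists and of Ggh (0.054). Of 29 lists tested for tissue, 19 passed in the main fit, 4 with an estimated correlation, and 16 to 21 with each array left out. Without pancreas genes in other lists 19 and, for genotype, 5 passed. The 3 genotype calls became 0 as deposited, without a filter, in normal arrays alone, in tumor arrays alone, with the mean per code and without the diet #1 arrays, 1 with every probe set and 1 with no replicate block, and 0 to 2 with each array left out: 0 without any normal array but the wild type one of diet #2 (2), 0 without the wild type tumor arrays of diets #1 and #3, 1 without that of diet #2, and 2 without any heterozygous tumor array. The 5 genotype lists became 8 with median scaling, 9 as deposited, 3 with the lower floor, 8 without a filter, 0 with an estimated correlation, and 0 to 8 with each array left out: 0, 2 and 8 without the heterozygous tumor, wild type tumor and wild type normal arrays of diet #2, 3 and 1 without the heterozygous normal and wild type tumor arrays of diet #1, and 2 without the heterozygous tumor array of diet #3. The interferon list reversed to 0.029 without the diet #1 arrays. The 3961 diet calls became 5947 as deposited, where scale differs by construction, 2003 in normal and 1144 in tumor arrays alone, and 2639 with the mean per code; without the diet #1 arrays the test is of diet #3 against #2 and called 1492, against 594 for that pair in the full fit; leaving out each array gave 3516 to 4122. The tissue by genotype count of 0 ranged from 0 to 1 with each array left out, the 1 coming without the heterozygous tumor array of diet #1. The 95 tissue by diet calls became 206 as deposited, 208 without a filter, 37 with the stricter filter, 34 without the diet #1 and 0 without the diet #2 arrays, and 44 to 331 with each array left out: 204 to 331 when it was any array of diet #1 and 44 to 54 when it was any of diet #2. Of 84 named genes, Edn1 reversed to -0.076 with median scaling, -0.035 with another probe set and ranged from -0.033 to 0.88 with each array left out; other probe sets reversed Car4 (-0.51) and Stmn2 (0.090). With single arrays left out, the calls of Slc34a2, Rrm1 and Egr1 were lost in 8 of 12 cases each, Ggh in 7, Stmn2 in 3, Reg1 in 2 and Phlda2 and Edn1 in 1, those of the proximal list in 5 and the T and NK and brush border lists in 3. Other values moved over 1.5 times: with median scaling Fabp6 (5.86), Cfi (4.31), Retnlb (3.87) and Cpa3 (2.29); with the higher floor Cfi (4.22), Retnlb (3.56), Saa3 (2.44), Cpa3 (1.91), Plaur (1.52), Cxcl5 (1.28), Ephx1 (-1.76), Ces1d (-1.42) and Car3 (-1.24); with other probe sets Reg3b (2.43), Lamb3 (2.32), Cpa3 (1.79), Col1a1 (0.89), Gstm6 (-1.80), Prxl2a (-0.23) and Reg1 (-0.62), the last 2 not passing; Ephx1 (-3.14) and Slc34a2 (3.53) without the heterozygous normal array of diet #1, and Slc34a2 (2.09) without that of diet #2. As deposited, Edn1 (0.15), Stmn2, H2-Ab1 and Cd4 (-0.49) did not pass, and with the higher floor Edn1 (0.031) did not. Floors limit dim genes: a fold from a floored array depends on the floor and the scaling.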

Other observations

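In the regenerative list, the interleukin 1 antagonist gene Il1rn was 7.16-fold, the growth factor gene Ereg 4.26-fold and Cldn4 4.43-fold higher in tumor, each in all 6 code pairs, and the cornified envelope gene Sprr1a was 5.27-fold higher. Among goblet cell genes Agr2 was 2.61-fold higher while Fcgbp differed by -0.19 ± 0.09 and Zg16 by -0.094 ± 0.067, neither past the threshold. In the brush border list the sugar transporter genes Slc2a2 (4.84-fold) and Slc5a1 (2.49-fold) fell, the peptidase gene Mep1a rose 2.64-fold, and villin (Vil1) differed by -0.12 ± 0.11. Genes in this paragraph were chosen after their values were seen.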
